A study of Mus musculus with 15 samples.

How the data were processed

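The series measured liver RNA of Mus musculus in 15 libraries, 5 from mice given T. cati eggs developed at 22 °C, 5 from mice given eggs developed at 37 °C and 5 from uninfected mice. Each library was placed in its group by its title. Total RNA was extracted with a Qiagen kit and sequenced on Illumina libraries, per the labels' protocols. The authors deposited 1 table of raw read counts, 1 row per gene symbol and 1 column per library. The genome build GRCm39 and the program DESeq2 are named in the submitters' processing notes, without roles or versions; the aligner, the counter, the annotation and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and counts of near-identical paralogs (the orosomucoid, serum amyloid A, eosinophil ribonuclease, Ugt2b, Cyp2a, Cyp2c, Cyp3a, Acot, Ces2, Gsta, Hsd3b, Mup and Ly6c families and the immunoglobulin segments) are uncertain to the extent that reads were shared.

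The table held 19986 genes after 3 lines with a pathway name and no values were set aside, and 0 columns lacked a sample. Of the symbols, 19564 matched the RefSeq gene table of assembly GRCm38.p6, which is another build than that of the files, so it was used for names only and no coordinates are given. Genes were kept with edgeR's filterByExpr by group (minimum count 10, minimum total count 15), which left 12708. Library sizes were scaled by TMM factors. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with all 15 libraries and 3 groups in one fit and no block, so that the groups share one estimate of the spread; the common biological coefficient of variation was 0.259. P-values were adjusted by Benjamini-Hochberg over all tested genes within each of the 3 comparisons, with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. For genes with 0 counts in all libraries of a group, the fold was computed against a floor of 3 counts summed over that group.

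The tests, samples, gene lists and alternatives were fixed before the data were examined, except where the closing section says otherwise. There were 46 gene lists for immune cells, liver cell types, liver metabolism, stress, sex-biased expression and tissues that a dissected liver could carry, with 825 of 882 listed members in the table (11 of them matched through another symbol after the table was seen). Lists with at least 4 tested members, 42 in all, were tested with camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, adjusted over these lists; camera with a correlation estimated from the data and fry were alternatives. In each list, genes were also adjusted over the list alone. The median and mean of a list's log2 fold changes differed in sign in 1, 5 and 4 of the lists in the 3 comparisons in order. The genes named are, per comparison, the 8 largest rises and 8 largest falls among genes past the threshold with an average log2 CPM of at least 1 and no overlap between the groups (predicted genes, pseudogenes and antigen receptor segments left out), up to 3 members with the smallest p of each list described, and 20 genes named whatever their result. Some genes that these rules select are not reported here.

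Each gene's GC content was taken from its longest transcript in GENCODE M21 (97.6% of tested genes had one). The trend of each library was a lowess curve (span 0.3) of the deviation of log2 CPM from the gene's mean on GC content, over 8785 genes; the slope given is that of a straight line. For the alternative with this trend removed, the curve entered the fit as an offset.

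The main test and the list test were tested on simulated data, with counts drawn for the real genes at the real depths and 200 genes changed, over 12708 genes. For 22 °C eggs against uninfected the test recovered 76% of genes changed by a log2 fold of 1 and 94% of those changed by 2, with 2 false calls. For 37 °C eggs against uninfected it recovered 66% and 92%, with 11 false calls, and for the infected groups against each other 66% and 94%, with 7 false calls. In the 3 comparisons 10 of 10 raised lists were called, and 0, 0 and 1 of 10 unchanged lists. The raised lists held only raised genes, and each gene was drawn independently, without a GC trend between libraries. The simulation therefore does not give the error rate for lists of correlated genes or under such a trend. The neutrophil list, for 1, had an estimated correlation of 0.69 for 22 °C eggs against uninfected.

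Alternatives were RLE size factors, library-size scaling only, DESeq2 1.42.0, limma-voom with sample quality weights, no filter on low counts, a filter of 1 CPM in 5 libraries, only the 2 groups compared, a replicate block, leaving out each library, and leaving out the 10 genes with the highest counts. Library pairs were compared by chi-square over their counts, and every pair differed by more than sampling noise. Plots were drawn with matplotlib 3.10.9.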

Results

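Liver RNA was sequenced from mice of 3 groups with 5 libraries each. One group had received 2500 eggs of Toxocara cati, the cat roundworm, that had developed at 22 °C for 5 weeks, the condition labelled as control. Another had received 2500 eggs that had developed at 37 °C for 2 weeks. The remaining group was uninfected, and infected mice were killed on day 21 to 22 of infection. In mice, larvae hatch in the gut and migrate through the liver and other organs without maturing. The libraries held between 30036582 counts (eggs_37C replicate 4) and 41339113 counts (eggs_37C replicate 2). Between 13336 and 14390 genes had at least 1 count per library, and 12708 were tested. At this depth 3 counts in one library correspond to 0.0726 to 0.0999 CPM, a limit that covers counting error only. The labels give no animal identifiers, so the p-values measure the spread between these libraries. All means are normalised CPM over 5 libraries with their SD, and fold changes are log2 values with their SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

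A pair of libraries held transcripts of another tissue and entered every comparison of their groups. In uninfected replicate 4 the 16 skeletal and cardiac muscle genes of a fixed list summed to 4707 CPM with 16 of 16 detected, against 0.6855 to 1.716 CPM in the other 14 libraries. In eggs_37C replicate 3, a library of the 37 °C egg group, 16 of 19 gallbladder and intestine genes were detected against 5 to 9 elsewhere, and Vil1, which encodes the microvillus protein villin, stood at 33.1 CPM against 0.157 to 0.317 CPM in the other libraries of that group. Mylpf, a myosin light chain gene of fast muscle, passed as lower after 22 °C eggs (-6.54 ± 1.64, adjusted p = 0.0257) with 183 CPM in uninfected replicate 4 and at most 0.642 CPM in the other uninfected libraries. Alb, which encodes serum albumin, took 9.754% of all counts in uninfected replicate 4 and 12.22% in eggs_37C replicate 3, within the 9.341% to 14.78% spanned by the 15 libraries. Libraries also differed in how expression followed the GC content of transcripts. The slope was -0.483 log2 units per 10 percentage points of GC in uninfected replicate 3, -0.359 and -0.357 in eggs_37C replicates 3 and 4, and between -0.085 and 0.305 in the other libraries. The mean slope was 0.149 ± 0.106 after 22 °C eggs, -0.076 ± 0.268 after 37 °C eggs and -0.073 ± 0.255 in uninfected mice (SD, n = 5). Exact two-sided permutation tests gave p = 0.0794 for 22 °C eggs against uninfected mice, 0.159 between the infected groups and 0.992 for 37 °C eggs against uninfected mice. In this order the Benjamini-Hochberg adjusted p was 0.238, 0.238 and 0.992.

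**Figure D1:**
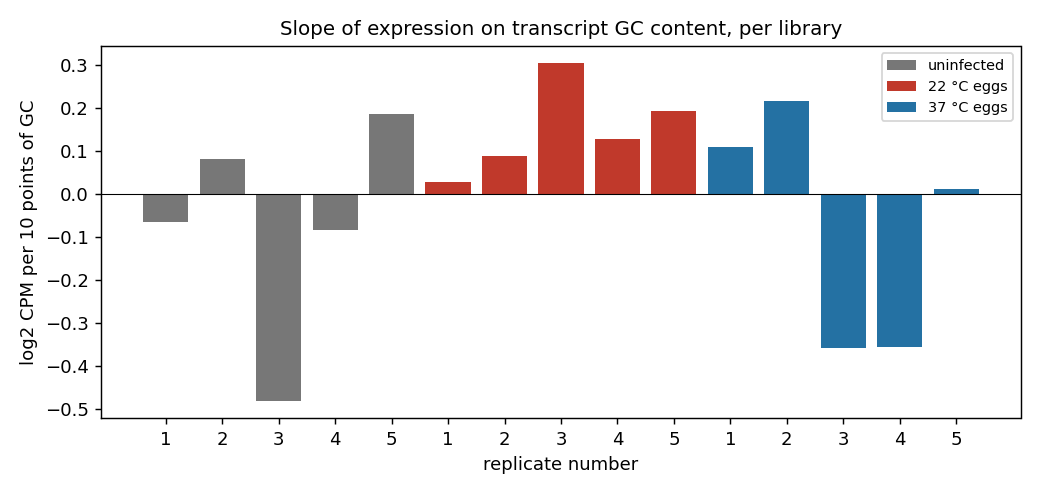
Slope of log2 CPM on transcript GC content in each of the 15 libraries, in log2 units per 10 percentage points of GC, as bars coloured by group. The lowest slopes are those of uninfected replicate 3 (-0.483) and eggs_37C replicates 3 and 4 (-0.359 and -0.357).

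The first comparison asked how the liver differed after infection with eggs kept at 22 °C. Higher transcripts were 11 of 13 of neutrophils, 7 of 8 of eosinophils, 5 of 7 of plasma cells, 16 of 21 of the acute phase and 20 of 34 of the matrix, and 10 of 29 of fatty acid oxidation fell. S100a9, which encodes a calcium-binding protein of neutrophils, went from 0.777 ± 0.324 to 63.8 ± 54.3 CPM, 80.5-fold. Prg2, which encodes eosinophil major basic protein, went from 0.0229 ± 0.0318 to 22.9 ± 15.6 CPM. Lcn2, which encodes the iron-sequestering protein lipocalin 2, went from 11 ± 4.66 to 330 ± 200 CPM, and Ppara, the nuclear receptor that controls fatty acid oxidation, fell from 37.9 ± 8.07 to 15 ± 3.99 CPM. In all, 496 genes were higher and 287 lower than in uninfected liver out of 12708 tested, 274 and 71 of them by at least 2-fold. The 5 libraries of each group did not overlap in 7.9% of tested genes, where chance gives 0.794%, and in 592 of the 783.

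Of the 13 neutrophil markers tested, 11 rose, 0 fell and 2 did not pass (13 rose adjusted over the list alone). The log2 fold changes were 6.33 ± 0.60 for S100a9 (adjusted p = 8.92e-06), 6.09 ± 0.60 for Retnlg, and 7.28 ± 0.82 for Mpo, which encodes myeloperoxidase of primary granules. Granule genes were also among the largest rises: Camp (7.78 ± 0.99), Prtn3 (7.37 ± 0.85), Ngp (6.97 ± 0.84) and Ltf (6.93 ± 0.84), which encode cathelicidin, proteinase 3, neutrophilic granule protein and lactoferrin. The list test, limma's camera, gave adjusted p = 3.28e-11, and adjusted p = 0.166 with an estimated correlation. Of the 8 eosinophil markers tested, 7 rose and 1 did not pass (8 adjusted over the list alone; camera adjusted p = 5.39e-10, and adjusted p = 0.152 with an estimated correlation). Prg2 rose by 9.68 ± 0.81 (adjusted p = 2.05e-06) and Ear2, an eosinophil-associated ribonuclease gene, by 1.52 ± 0.21. The uninfected means of Prg2 and of Mpo (5 counts over the group) lay below the CPM of 3 counts in a library. The sizes of these folds are therefore uncertain. Epx, which encodes eosinophil peroxidase, and Ear6 had 0 counts in all 5 uninfected libraries, and against a floor of 3 counts over the group they were at least 238-fold and 170-fold higher (4.35 ± 3.04 and 3.11 ± 2.5 CPM).

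Monocyte and macrophage markers showed 6 rises and 0 falls among 21 (10 rises adjusted over the list alone). They were led by Ly6c2 at 5.21 ± 0.39 (adjusted p = 1.7e-06), a surface antigen of inflammatory monocytes, with the chemokine receptor gene Ccr2 at 1.64 ± 0.28 and the lipid-sensing receptor gene Trem2 at 2.16 ± 0.39. The list test gave adjusted p = 3.24e-07, and adjusted p = 0.166 with an estimated correlation. Among 11 genes of alternatively activated macrophages 5 rose (7 adjusted over the list alone), among them Chil3, which encodes the chitinase-like protein Ym1, at 7.69 ± 1.48 (adjusted p = 0.00529), Alox15 at 2.85 ± 0.67 and the eotaxin gene Ccl24 at 0.97 ± 0.21. This list test gave adjusted p = 0.000457, and adjusted p = 0.166 with an estimated correlation. Retnla, which encodes RELM-alpha, had a log2 fold change of 4.32 ± 1.31 that did not pass (adjusted p = 0.0585), and Arg1 stood at 1660 ± 192 against 1730 ± 454 CPM (adjusted p = 0.852). Arg1 was also on the fixed list of hepatocyte markers, so its value in whole liver does not show whether macrophage expression changed. Of 9 tested type 2 cytokine, chemokine and receptor genes 3 rose (3 adjusted over the list alone). These were Ccl24, the decoy receptor gene Il13ra2 at 3.95 ± 0.56 (adjusted p = 0.000386) and Il1rl1, the receptor of interleukin 33, at 2.71 ± 0.75. As a list, type 2 genes had adjusted p = 0.00777, and adjusted p = 0.166 with an estimated correlation.

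The cytokine transcripts themselves were near or below the detection limit. Summed over 5 libraries, Il4 had 15 counts after 22 °C eggs and 3 in uninfected mice, a ratio of 4.83. A 95% counting interval of the 3 uninfected counts alone put this ratio at 1.65 to 23.4. That range takes the 15 counts as known and leaves out the spread between libraries, so it is too narrow for the ratio. Il4 did not pass the filter on low counts and was not tested. Il10, also not tested, had 29 counts against 0, at least 9-fold higher against the floor of 3 counts. That fold likewise leaves out the spread between libraries. Il5 had 0 against 5 counts, Ifng 7 against 2 and Foxp3 15 against 10, and Il13 had 0 in both, so that differences in Il5, Ifng, Foxp3 and Il13 were not detectable at this depth.

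Of 7 plasma cell genes 5 rose (6 adjusted over the list alone). Jchain, which encodes the chain that joins immunoglobulin polymers, went from 1.41 ± 0.64 to 204 ± 61.3 CPM (log2 fold change 7.18 ± 0.96, adjusted p = 0.000308), with Irf4 at 3.54 ± 0.63 and Mzb1 at 4.35 ± 0.87. The list test gave adjusted p = 7.09e-07, and adjusted p = 0.0676 with an estimated correlation. Of 12 B cell markers 5 rose (6 adjusted over the list alone), including Ms4a1 (2.31 ± 0.56, adjusted p = 0.021), Cd79a (2.50 ± 0.61) and Fcrla (1.78 ± 0.45). As a list, B cell markers had adjusted p = 0.000367, and adjusted p = 0.33 with an estimated correlation. Of 17 dendritic cell and MHC class II genes 3 rose (5 adjusted over the list alone), Fscn1 (0.98 ± 0.22, adjusted p = 0.0149), Cd74 (0.88 ± 0.21) and H2-Ab1 (0.80 ± 0.22). As a list, antigen presentation genes had adjusted p = 0.000457, and adjusted p = 0.249 with an estimated correlation. Cd4 stood at 0.648 ± 0.185 against 0.669 ± 0.332 CPM (adjusted p = 0.967). Ly6d, a surface antigen gene outside these lists, was among the largest rises at 6.37 ± 0.77 (adjusted p = 0.000109). Among cell cycle genes 2 of 34 rose (2 adjusted over the list alone), Top2a (1.69 ± 0.41, adjusted p = 0.0205) and Mki67 (1.69 ± 0.45, adjusted p = 0.034). As a list, cell cycle genes had adjusted p = 6.24e-05, and adjusted p = 0.52 with an estimated correlation.

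Hepatic acute-phase genes formed the list with the smallest p. Whole-liver RNA does not show in which cells its members rose. Of 21 acute-phase genes 16 rose and 0 fell (18 adjusted over the list alone), among them Lcn2 (4.90 ± 0.41, adjusted p = 2.05e-06), Orm3 (2.82 ± 0.25), Orm2 (5.42 ± 0.58) and Saa1 (4.81 ± 0.59), which encode lipocalin 2, 2 orosomucoids and serum amyloid A. The list test gave adjusted p = 3.84e-19, and adjusted p = 0.146 with an estimated correlation. Of 28 complement and coagulation genes 9 rose and 1 fell (11 and 1 adjusted over the list alone). Among them Hc and C9, components of the membrane attack pathway, rose by 1.01 ± 0.12 (adjusted p = 7.42e-05) and 1.06 ± 0.14. As a list, complement genes had adjusted p = 7.94e-08, and adjusted p = 0.188 with an estimated correlation. Of 34 extracellular matrix genes 20 rose and 0 fell (26 adjusted over the list alone). Postn, which encodes periostin, rose by 2.41 ± 0.20 (adjusted p = 2.05e-06), Col6a2 by 3.05 ± 0.40, Col6a1 by 2.28 ± 0.31, Col1a1 by 2.04 ± 0.43 and Col3a1 by 1.84 ± 0.32. The list test gave adjusted p = 5.65e-18, and adjusted p = 0.166 with an estimated correlation.

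Several lists of metabolic genes were lower. Of 29 genes of fatty acid oxidation and PPAR-alpha targets 10 fell and 0 rose (17 fell adjusted over the list alone). They included Ppara (-1.33 ± 0.18, adjusted p = 0.000368), Fabp1, the liver fatty acid-binding protein gene (-0.83 ± 0.16), and Acot2 (-0.93 ± 0.21). As a list, fatty acid oxidation genes had adjusted p = 2.12e-11, and adjusted p = 0.166 with an estimated correlation. Pdk4, which encodes a kinase that restrains pyruvate oxidation, fell by 2.19 ± 0.52 (adjusted p = 0.0196), from 46.3 ± 49.5 CPM in uninfected mice. Uninfected replicate 4, which held muscle transcripts, stood at 133 CPM and the other 4 at 15.5 to 38.4 CPM; without the 2 libraries that held muscle or intestine transcripts the log2 fold change was -1.26 (adjusted p = 0.0367). Of 37 cytochrome P450 and drug metabolism genes 6 fell and 2 rose (9 and 2 adjusted over the list alone). Among them Ugt2b1 (-1.01 ± 0.19, adjusted p = 0.00408) and Ces2a (-0.89 ± 0.17) were lower and Cyp2c70 (0.74 ± 0.15) higher. As a list, drug metabolism genes had adjusted p = 0.00101, and adjusted p = 0.398 with an estimated correlation. Cyp2e1 (-0.13 ± 0.14) and Cyp1a2 (-0.29 ± 0.21) did not pass. Among 19 bile acid genes 1 fell, the transporter gene Slco1a4 (-0.73 ± 0.21, adjusted p = 0.0432; 5 fell adjusted over the list alone). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 143 ± 95 against 92 ± 60.4 CPM (adjusted p = 0.554). As a list, bile acid genes had adjusted p = 0.0067, and adjusted p = 0.422 with an estimated correlation. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in all 15 libraries. Of 21 genes known for higher expression in female liver 4 fell (4 adjusted over the list alone), among them Cyp2c40 (-0.71 ± 0.16, adjusted p = 0.0165) and Abcd2 (-0.80 ± 0.19). As a list, female-biased genes had adjusted p = 0.000201, and adjusted p = 0.326 with an estimated correlation. Other large falls were Ptgds (-2.90 ± 0.46), Clec2h (-2.39 ± 0.43), Nr2c2 (-2.06 ± 0.32), Hsd17b6 (-1.84 ± 0.19), Elovl3 (-1.81 ± 0.37) and Ntrk2 (-1.71 ± 0.24), at adjusted p of 2.41e-05 to 0.00833. Hepatocyte markers gave 0 calls among 22 (1 higher and 1 lower adjusted over the list alone; list adjusted p = 0.575), and Alb stood at 111000 ± 15700 against 119000 ± 21100 CPM (adjusted p = 0.759).

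**Figure D2:**
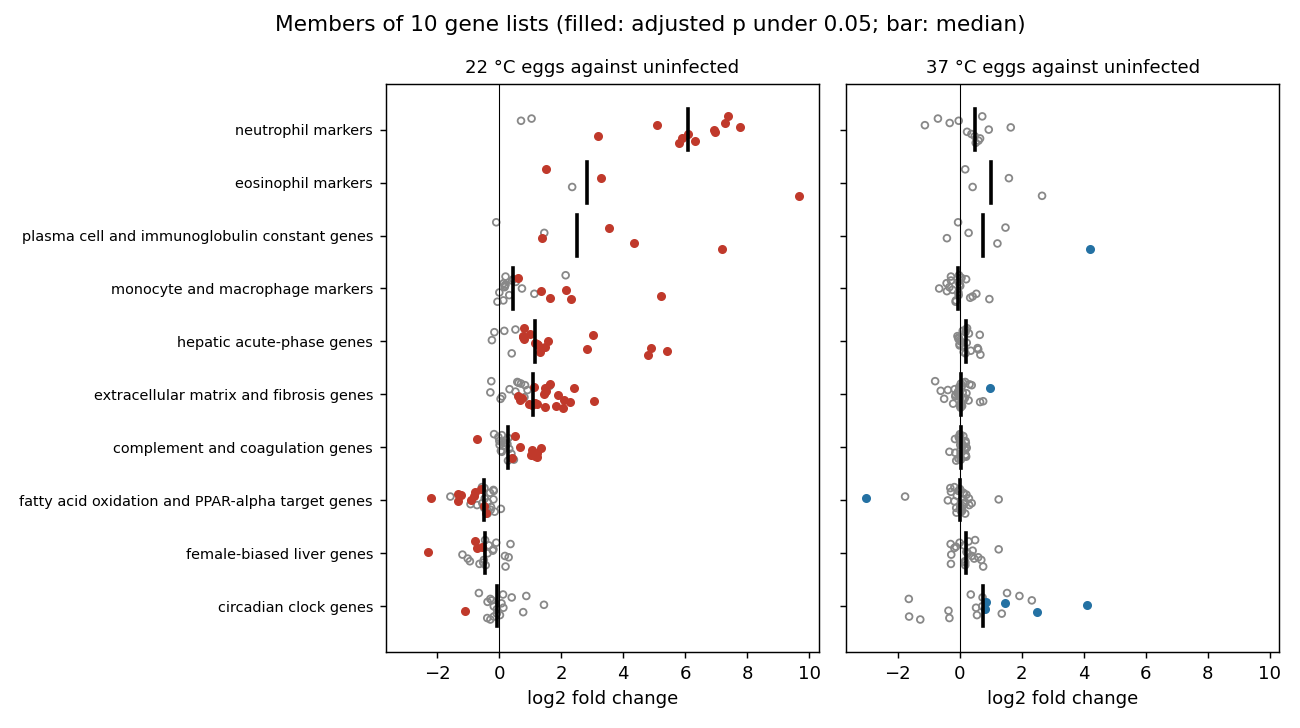
Log2 fold changes of the members of 10 gene lists, after 22 °C eggs (left) and after 37 °C eggs (right), each against uninfected liver. Each circle is a gene, filled where its adjusted p passed the threshold, and the bar is the median; genes with 0 counts in a whole group are left out. Neutrophil markers had 11 of 13 members filled after 22 °C eggs and 0 of 13 after 37 °C eggs.

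In this comparison 13 of 42 lists were higher and 5 lower by camera with the preset correlation, 0 with an estimated correlation, and 14 by fry, a rotation test of each list on its own. The count of higher genes fell to 256 without eggs_22C replicate 3 and 306 without eggs_22C replicate 5. The count of lower genes was 189, 131, 191 and 130 without eggs_22C replicates 2, 3, 4 and 5, 177 and 187 without uninfected replicates 1 and 3, and 454 without eggs_22C replicate 1. By DESeq2 560 and by limma-voom 465 were lower.

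The second comparison asked how the liver differed after infection with eggs kept at 37 °C. Of 19 clock genes 5 passed as higher, 4 genes of gluconeogenesis and insulin response fell, and the neutrophil, eosinophil, acute-phase, matrix and plasma cell lists held 0 or 1 call each. Dbp, a clock-controlled transcription factor gene, went from 3.85 ± 3.57 to 66.3 ± 28.9 CPM, 17.3-fold. G6pc, which encodes the catalytic subunit of glucose-6-phosphatase, fell from 533 ± 84 to 90.9 ± 44.6 CPM. In all 28 genes were higher and 20 lower than in uninfected liver, 46 of the 48 with no overlap between groups, and 1102 had an unadjusted p under 0.05 where 635 are the chance number.

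Of 19 circadian clock genes 5 rose and 0 fell (13 rose and 4 fell adjusted over the list alone). The log2 fold changes were 4.11 ± 0.64 for Dbp (adjusted p = 0.007), 2.50 ± 0.46 for Per3, 1.47 ± 0.24 for Tef, 0.85 ± 0.18 for Hlf and 0.83 ± 0.12 for Cry2 (adjusted p = 0.00625). The list test gave adjusted p = 8.84e-07, and adjusted p = 0.0702 with an estimated correlation, and fry gave adjusted p = 0.0161. Wee1, a cell cycle kinase gene under clock control, rose by 2.33 ± 0.36 (adjusted p = 0.007). Other rises were Cish, a feedback inhibitor gene of STAT5 signalling (1.63 ± 0.32), Cyp2a5 (1.28 ± 0.23), Rgs3 (1.18 ± 0.18) and Irf1 (0.63 ± 0.12), at adjusted p of 0.007 to 0.0331.

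Of 18 gluconeogenesis and glycolysis genes 4 fell and 0 rose (4 fell and 1 rose adjusted over the list alone). They included G6pc (-2.55 ± 0.36, adjusted p = 0.00625) and Igfbp1, the gene of an insulin-repressed binding protein (-3.48 ± 0.69, adjusted p = 0.0363). The others were the insulin receptor substrate gene Irs2 (-1.32 ± 0.25) and Pck1, which encodes a cytosolic enzyme of gluconeogenesis (-1.26 ± 0.25). The list did not pass (adjusted p = 0.0676). Pdk4 (-3.03 ± 0.54), Adcy1 (-2.34 ± 0.40), Bcl6 (-2.22 ± 0.46), Tat, which encodes tyrosine aminotransferase (-1.49 ± 0.27), and Trp53inp1 (-1.36 ± 0.21) also fell, at adjusted p of 0.007 to 0.0462. The uninfected mean of Pdk4 (46.3 ± 49.5 CPM) rested on uninfected replicate 4, and without the 2 libraries its log2 fold change was -1.96 (adjusted p = 0.0648).

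Neutrophil (13 tested), eosinophil (8), acute-phase (21) and monocyte and macrophage (21) genes gave 0 calls each, also adjusted over the list alone. S100a9 stood at 1.21 ± 0.516 CPM and Lcn2 at 16.5 ± 4.66 CPM, and Epx had 0 counts in all 5 libraries of both groups. Saa1 was at 48.1 ± 14.2 against 30.1 ± 8.44 CPM (adjusted p = 0.844). The acute-phase list passed camera as higher (adjusted p = 0.0288, and adjusted p = 0.903 with an estimated correlation) with 0 members past the threshold in either adjustment. Among all genes 1102 had an unadjusted p under 0.05, and DESeq2 called 95 higher and 88 lower. Of 34 matrix genes 1 rose, Postn (0.98 ± 0.19, adjusted p = 0.0331, and 0.000291 to 0.181 over all alternatives; 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.995); Col1a1 (0.03 ± 0.42) and Col3a1 (0.08 ± 0.31) did not pass. Chil3 (5.33 ± 1.47, adjusted p = 0.153), Retnla (4.40 ± 1.31, adjusted p = 0.204), Prg2 (2.66 ± 1.22, adjusted p = 0.547) and Mki67 (0.91 ± 0.45, adjusted p = 0.61) did not pass. In this group eggs_37C replicate 5 held 22.4 CPM of Chil3 against at most 0.606 CPM in the other libraries, and 25.6 CPM of Retnla against 0.222 to 2.95 CPM. Il4, Il5 and Il13 had 0 counts after 37 °C eggs, Ifng had 5, Foxp3 20 and Il10 19. With a floor of 3 counts for the 0 counts of uninfected mice, Il10 was at least 6-fold higher. Of its 19 counts, 13 were in eggs_37C replicate 4. These genes did not pass the filter on low counts and were not tested.

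Jchain rose by 4.22 ± 0.87 (adjusted p = 0.0422), the 1 call among 7 plasma cell genes (1 adjusted over the list alone; list adjusted p = 0.0795). It stood at 109 CPM in eggs_37C replicate 3, the library with intestine transcripts, and at 4.47 to 6.39 CPM in the other 4, against 1.41 ± 0.64 CPM in uninfected mice. Without that library and uninfected replicate 4 its log2 fold change was 1.84 (adjusted p = 0.0514; 0.000103 to 0.333 over all alternatives). B cell markers gave 0 calls among 12 (7 rose adjusted over the list alone). As a list, B cell genes had adjusted p = 0.00385, and adjusted p = 0.903 with an estimated correlation. The B cell gene Ms4a1 stood at 8.92 CPM in eggs_37C replicate 5 and at 1.43 to 2.2 CPM in the other libraries of that group. Other lists past camera as higher were cell cycle (34 tested, 0 calls, adjusted p = 0.0164), bile duct markers (14 tested, 0 calls, adjusted p = 0.0461) and female-biased genes (21 tested, 0 calls, 2 rose adjusted over the list alone, adjusted p = 0.0245). Those past camera as lower were immediate early genes (16 tested, 0 calls, 5 fell adjusted over the list alone, adjusted p = 0.0139), stellate cell markers (15 tested, 0 calls, adjusted p = 0.0461) and male-biased genes (16 tested, 0 calls, adjusted p = 0.00385). With an estimated correlation, adjusted p was 0.0702 for male-biased genes and 0.903 for each of the other 5.

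Of these 42 lists 6 were higher and 3 lower by camera with the preset correlation, 0 with an estimated correlation and 1 by fry. Without the 2 libraries that held muscle or intestine transcripts, 0 genes were higher and 1, G6pc, was lower (-2.82, adjusted p = 0.0299; 1.47e-08 to 0.0299 over all alternatives). Higher genes numbered 15, 14 and 10 without eggs_37C replicates 1, 2 and 3 and 12, 17, 7 and 14 without uninfected replicates 1, 3, 4 and 5. Lower genes numbered 9, 11, 8 and 10 without eggs_37C replicates 1 to 4, 34 without eggs_37C replicate 5, and 12, 13, 9 and 12 without uninfected replicates 1, 3, 4 and 5.

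The last comparison set the 2 infected groups side by side and so tested whether the temperature and length of egg development went with a different liver response. After 37 °C eggs 12 of 13 neutrophil, 6 of 8 eosinophil, 15 of 21 acute-phase, 20 of 34 matrix, 8 of 28 complement and 5 of 7 plasma cell genes were lower than after 22 °C eggs. Genes of fatty acid oxidation were higher in 11 of 29 cases, of drug metabolism in 8 of 37 and of the clock in 9 of 19. S100a9 stood at 1.21 ± 0.516 against 63.8 ± 54.3 CPM, Lcn2 at 16.5 ± 4.66 against 330 ± 200 CPM and Ppara at 41.8 ± 4.49 against 15 ± 3.99 CPM. Of 12708 genes 444 were higher and 566 lower after 37 °C eggs, 93 and 273 of them by at least 2-fold, and 684 of the 1010 had no overlap between the groups.

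**Figure D3:**
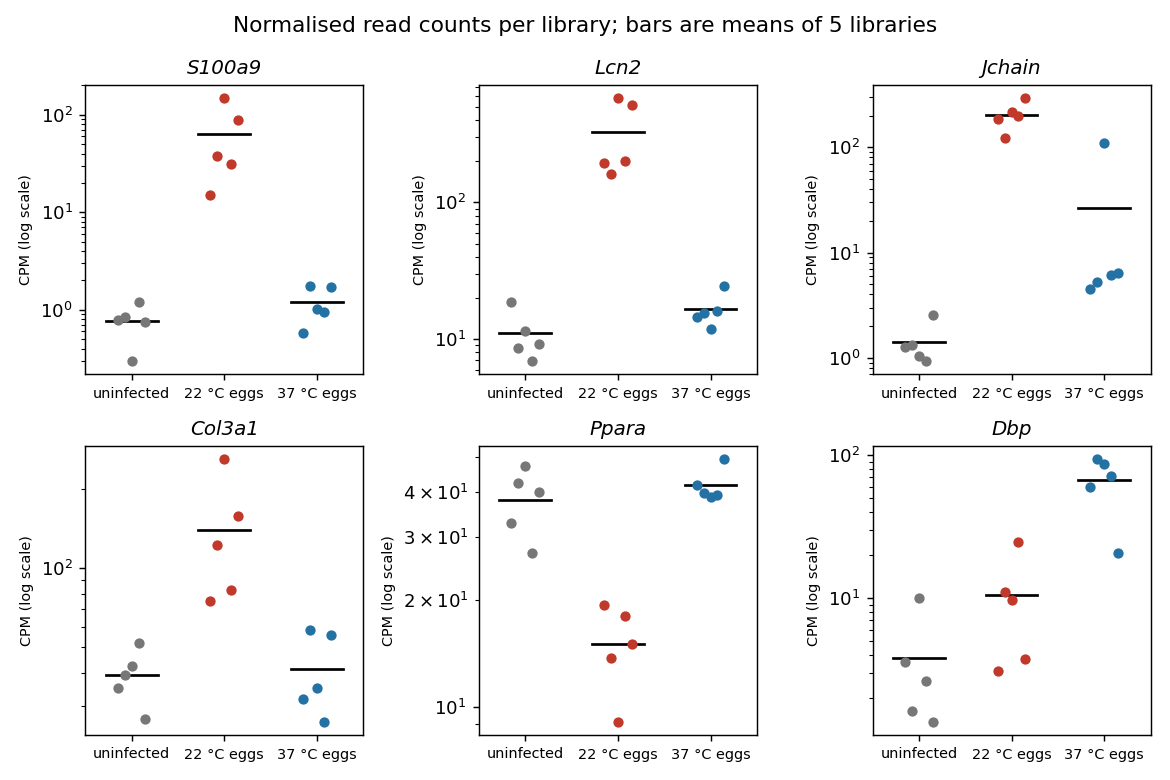
Normalised read counts (CPM, log scale) of 6 genes in the 15 libraries, by group; points are libraries and bars are means of 5. S100a9, Lcn2 and Col3a1 are highest in the 22 °C egg libraries, Ppara is lowest there, the mean of Dbp is highest after 37 °C eggs, and the 109 CPM point of Jchain is eggs_37C replicate 3.

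Of 13 neutrophil markers 12 were lower after 37 °C eggs (13 adjusted over the list alone), with log2 fold changes of -5.72 ± 0.57 for S100a9 (adjusted p = 5.21e-05), -5.71 ± 0.58 for Retnlg, -5.28 ± 0.64 for S100a8 and -7.61 ± 0.84 for Mpo. The Mpo mean after 37 °C eggs (0.023 CPM) lay below the CPM of 3 counts in a library, so the size of that fold is uncertain. Granule genes had values of -6.73 ± 0.82, -6.64 ± 0.80, -6.13 ± 0.85 and -6.00 ± 0.78 for Ngp, Prtn3, Camp and Ltf. Of 8 eosinophil markers 6 were lower (8 adjusted over the list alone): Prg2 by -7.02 ± 0.64 (adjusted p = 2.03e-05), Ear2 by -1.34 ± 0.21, and Epx, at 0 counts after 37 °C eggs, at least 253-fold. The list tests gave adjusted p = 1.38e-11 for neutrophil markers and 6.45e-09 for eosinophil markers, and adjusted p = 0.16 and 0.133 with an estimated correlation. Of 21 monocyte and macrophage markers 7 were lower (9 adjusted over the list alone), led by Ly6c2 (-4.79 ± 0.38, adjusted p = 6.5e-06), Trem2 (-2.39 ± 0.39) and the integrin gene Itgax (-1.75 ± 0.32). As a list, monocyte markers had adjusted p = 2.34e-08, and adjusted p = 0.133 with an estimated correlation. Of 7 plasma cell genes 5 were lower (6 adjusted over the list alone), among them Mzb1 (-3.13 ± 0.79, adjusted p = 0.0246), Jchain (-2.95 ± 0.77, with 109 CPM in eggs_37C replicate 3) and Derl3 (-1.78 ± 0.39). As a list, plasma cell genes had adjusted p = 4.78e-06, and adjusted p = 0.118 with an estimated correlation.

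Of 17 dendritic cell and MHC class II genes 5 were lower (9 lower and 1 higher adjusted over the list alone), including Fscn1 (-0.98 ± 0.22, adjusted p = 0.0141), Cd74 (-0.84 ± 0.21) and H2-Ab1 (-0.83 ± 0.22). As a list, class II genes had adjusted p = 0.000121, and adjusted p = 0.177 with an estimated correlation. Of 11 genes of alternatively activated macrophages 3 were lower (3 adjusted over the list alone). They were Tgm2 (-1.49 ± 0.35, adjusted p = 0.0167), Clec10a (-1.90 ± 0.55) and Ccl24 (-0.72 ± 0.21). Of 9 type 2 genes 2 were lower (2 adjusted over the list alone), Ccl24 and Il13ra2 (-2.48 ± 0.50, adjusted p = 0.00766). These lists had adjusted p = 0.00346 and 0.00988, and adjusted p = 0.179 and 0.162 with an estimated correlation. Retnla (0.08 ± 1.05, adjusted p = 0.972, with 25.6 CPM in eggs_37C replicate 5) and Chil3 (-2.36 ± 1.01, adjusted p = 0.16) did not pass. Chil3 stood at 22.4 CPM in eggs_37C replicate 5 and at 0.114 to 0.606 CPM in the other libraries of that group. Arg1 (0.20 ± 0.15), also a listed hepatocyte marker, Cd4 (0.06 ± 0.42) and Mki67 (-0.78 ± 0.43) did not pass either, and B cell markers gave 0 calls among 12.

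Of 21 acute-phase genes 15 were lower (16 lower and 1 higher adjusted over the list alone), with Lcn2 at -4.32 ± 0.40 (adjusted p = 2.03e-05), Orm2 at -5.06 ± 0.57, Orm3 at -2.22 ± 0.24 and Saa1 at -4.13 ± 0.57. Of 34 matrix genes 20 were lower and 0 higher (28 lower adjusted over the list alone), among them Postn (-1.42 ± 0.19, adjusted p = 0.000426), the gelatinase gene Mmp2 (-1.49 ± 0.24), Col6a2 (-2.29 ± 0.38), Col1a1 (-2.01 ± 0.43) and Col3a1 (-1.76 ± 0.31). Of 28 complement and coagulation genes 8 were lower and 1 higher (12 and 1 adjusted over the list alone), with C8a (-1.36 ± 0.21) and Hc (-0.81 ± 0.12, adjusted p = 0.000708). The list tests gave adjusted p = 1.34e-14, 3.59e-18 and 2.18e-06 in this order, and adjusted p = 0.133, 0.16 and 0.227 with an estimated correlation. Of 16 immediate early and heat shock genes 5 were lower (7 adjusted over the list alone), including Gadd45g (-2.78 ± 0.52, adjusted p = 0.00497), Hspa1a (-2.66 ± 0.56) and Dusp1 (-2.21 ± 0.51). As a list, immediate early genes had adjusted p = 0.00032, and adjusted p = 0.338 with an estimated correlation.

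Of 29 genes of fatty acid oxidation and PPAR-alpha targets 11 were higher after 37 °C eggs and 0 lower (19 higher adjusted over the list alone), with Ppara at 1.47 ± 0.18 (adjusted p = 0.000214) and Fabp1 at 0.74 ± 0.16; Fabp2, also expressed in intestine, was at 1.44 ± 0.29. The list had adjusted p = 2.28e-09, and adjusted p = 0.162 with an estimated correlation. Of 37 cytochrome P450 and drug metabolism genes 8 were higher and 1 lower (9 and 1 adjusted over the list alone), including Ces2a (0.87 ± 0.17, adjusted p = 0.00662), Cyp3a25 (0.93 ± 0.19) and Ugt2b1 (0.82 ± 0.19). As a list, cytochrome P450 and related genes had adjusted p = 9.73e-05, and adjusted p = 0.329 with an estimated correlation. Of 21 female-biased genes 6 were higher (9 adjusted over the list alone), with Acot3 at 1.45 ± 0.32 (adjusted p = 0.0123) and Abcd2 at 1.08 ± 0.20. As a list, female-biased genes had adjusted p = 8.5e-08, and adjusted p = 0.162 with an estimated correlation. Clec2h (3.10 ± 0.44), Ptgds (2.09 ± 0.45), Nr2c2 (1.95 ± 0.32), Wee1 (1.88 ± 0.35), Hsd17b6 (1.76 ± 0.19) and Gse1 (1.75 ± 0.33) were among the largest rises. The rise of Vil1 (5.12 ± 1.43, adjusted p = 0.0375) rested on eggs_37C replicate 3, which held 33.1 CPM. Alb (0.12 ± 0.17), Cyp7a1 (0.73 ± 0.60), Cyp2e1 (0.34 ± 0.15) and Cyp1a2 (0.42 ± 0.21) did not pass.

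Of 19 clock genes 9 were higher and 1 lower after 37 °C eggs (11 and 3 adjusted over the list alone), with Cry2 at 0.91 ± 0.12 (adjusted p = 0.000329), Hlf at 1.24 ± 0.18 and Tef at 1.40 ± 0.24. The list test gave adjusted p = 1.02e-05, and adjusted p = 0.133 with an estimated correlation. Of 18 gluconeogenesis and glycolysis genes 2 were higher and 4 lower (3 and 5 adjusted over the list alone; list adjusted p = 0.561), among them G6pc (-2.15 ± 0.35, adjusted p = 0.00207) and Igfbp1 (-3.81 ± 0.70), which fell.

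The calls of the 3 comparisons overlapped. Of the 496 genes higher after 22 °C eggs than in uninfected mice, 330 were also higher than after 37 °C eggs, and of the 287 lower genes 154 were also lower; both comparisons use the same 5 libraries of the 22 °C egg group, so an overlap is expected from these alone. Genes past the threshold in the same direction in both infected groups against uninfected mice were 7 higher and 4 lower. The higher ones were Postn, Cish, Jchain, Plekhg5 and the immunoglobulin light chain segments Iglv1, Iglv3 and Igkv8-16, and the lower ones Pdk4, Trp53inp1, Arhgef3 and Tcim; those outside the naming rule were named after their values were seen. Without the 2 libraries that held muscle or intestine transcripts G6pc was the 1 gene past the threshold after 37 °C eggs, so the shared calls were not kept. In 100 simulations all 15 libraries, the uninfected ones included, were drawn from the uninfected mean. In these 0.02 genes were shared on average and at most 1. Unchanged groups give few calls, so few shared calls follow. A real 22 °C response beside an unchanged 37 °C group was not simulated. Independent calls would share 1.09 higher and 0.452 lower genes, which takes no account of the shared uninfected libraries. Across genes, which are not independent replicates, the log2 fold changes of both infected groups had a correlation of 0.417 and a covariance of 0.0876, against 0.501 ± 0.0137 and 0.0416 ± 0.0017 (SD) in the simulations. The correlation and covariance were 0.149 and 0.0383 on average over 20 splits that gave each comparison its own uninfected libraries, and so fewer than 5.

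Between the infected groups 5 of 42 lists were higher and 12 lower by camera with the preset correlation, 0 with an estimated correlation and 15 by fry. Without the 2 libraries that held muscle or intestine transcripts 185 genes were higher and 327 lower; leaving out eggs_22C replicate 3 gave 167 and 259, eggs_22C replicate 5 gave 168 and 273, eggs_37C replicate 3 gave 202 and 314, and eggs_37C replicate 4 gave 189 and 280.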

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

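The tests of other splits, of the libraries with muscle or intestine transcripts, of hepatocyte share, of blood content, of clock phase and of granulocyte precursors were chosen only after the results they bear on had been seen. The GC correction was also added after the data were seen, when each library's GC slope was known and its corrected results were not.

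Of the 12708 genes, 1010 differed between the infected groups, which share the uninfected group, so that their differences from uninfected mice were unequal, and 479 of these calls were kept without the 2 libraries that held muscle or intestine transcripts. Of the 76 tested neutrophil, eosinophil, acute-phase and matrix genes, 53 were among them and lower after 37 °C eggs, with a median log2 fold change of -1.76. The tables argue against a GC trend between libraries as the whole cause, since 53 of the 53 still passed with it removed (median -1.74), and against muscle and intestine RNA in 2 libraries, since without these the median was -1.71 and 45 still passed. A lower share of hepatocyte RNA after 22 °C eggs, with the other liver cells in fixed proportions, would raise the markers of all of these alike. The 60 Kupffer, stellate, endothelial and bile duct markers had a median log2 difference of 0.02, and 21 granulocyte markers one of 6. These values argue against that case only. A changed make-up of the other cells could lower the hepatocyte share without raising these markers, and was not tested. More blood of unchanged make-up would raise erythroid genes as it does granulocyte markers. The 6 erythroid genes had a median difference of 0.3 (0.05 to 0.87). A candidate explanation that stays open is a weaker infection after 37 °C eggs, with fewer larvae reaching the liver, which these data do not measure; temperature and length of development changed together and cannot be separated here.

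The 9 clock and gluconeogenesis genes that passed after 37 °C eggs against uninfected mice had a median absolute log2 fold change of 1.47. With the GC trend removed the median was 1.46 and 9 of 9 still passed, which argues against that trend; without the 2 libraries that held muscle or intestine transcripts it was 1.35, but only 1 of 9 still passed among 4 libraries per group, so the sizes were similar and the calls were not kept. A difference in time of day or feeding at sampling would move the clock genes of opposite phases in opposite senses, and 11 of 11 did, among them the called rises that prompted the test: Arntl, Clock, Npas2 and Nfil3 had negative log2 fold changes (-0.33 to -1.64), and those of Dbp, Tef, Hlf, Per2, Per3, Ciart and Nr1d2 were positive (0.73 to 4.11), and 4 passed. Against 22 °C eggs Clock (0.06) did not follow, and after 22 °C eggs against uninfected mice 0 of 19 clock genes rose and 1 fell (list adjusted p = 0.475). These genes oscillate as one system, and any shift of its phase would give the same signs. Sampling time is not given in the labels, so whether it differed between the groups is unknown. A difference in sampling time and an effect of infection on the clock cannot be told apart here.

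In 100 of the 126 possible splits of 10 libraries, fitted with the 2 groups only, 1 split gave as many genes as the real 753 between 22 °C eggs and uninfected mice, the real one itself, and the highest other split gave 1. The same held between the infected groups, with 1007 genes in the real split, 1 split as large and 1 gene in the highest other. Between 37 °C eggs and uninfected mice the real split gave 26 genes and 2 splits were as large, the real one included. That share is under 0.05, but the highest other split gave 778 genes, many times the real count, so the count does not set the real groups apart from a structure that they do not follow: eggs_37C replicates 1, 2 and 5 and uninfected replicates 2 and 5 stood against the rest. With the GC trend removed this split gave 1 gene while the real groups gave 74, so a GC trend between libraries may underlie it; the split was picked for its count, and whether the trend came from library preparation or RNA quality was not tested.

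Further series were examined for a single library standing apart within its group of 5, on log2(CPM + 0.1) for genes with a group mean of at least 1 CPM, by Dixon's ratio with a critical value of 0.71. Of 385 series 20 passed where chance gives about 1 in 20, or 19.2, so the number as a whole was near chance. In uninfected replicate 4 the muscle genes summed to 4707 CPM against 0.726 to 1.09 CPM in the other uninfected libraries, and Mylpf stood at 183 CPM. In eggs_37C replicate 3, Vil1 stood at 33.1 and Jchain at 109 CPM, and Saa1 was lowest at 24.3 against 46.2 to 59.5 CPM.

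In eggs_37C replicate 5, Chil3 stood at 22.4 against at most 0.606 CPM, the B cell gene Ms4a1 at 8.92 against 1.43 to 2.2 CPM, and Pdk4 at 12.6 against 3.17 to 4.6 CPM. In eggs_22C replicate 3, Ccr2 (8.53 CPM), Itgax (4.59 CPM) and Asns (17.6 CPM) were highest and Elovl3 (0.642 CPM), Cyp1a2 (219 CPM) and Slco1b2 (409 CPM) lowest in the group. Cry2 was lowest in eggs_22C replicate 5 at 11.4 CPM and highest in eggs_37C replicate 2 at 34.8 CPM. Ntrk2 stood at 13.6 against 28.6 to 33 CPM in uninfected replicate 2, and Trp53inp1 at 66.3 against 51.8 to 54.9 CPM in eggs_37C replicate 4. In eggs_37C replicate 1, ND2 stood at 6488 CPM and mitochondrially encoded genes took 8.32% of counts against 10.6% to 11.4% in the rest of the group.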

How the results depend on the processing

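The fits without the 2 libraries that held muscle or intestine transcripts and with the GC trend removed were chosen after the data were seen; the others were planned. The direction of each count-level comparison below refers to higher and lower genes, and where a count moved beyond 1.5 times the cause was not tested, except that leaving out libraries lowers the number of samples. For 22 °C eggs against uninfected mice the count of lower genes was 560 by DESeq2 and 465 by limma-voom with quality weights. For 37 °C eggs against uninfected mice higher and lower genes numbered 95 and 88 by DESeq2, 14 and 12 in a fit of only the 2 groups, 0 and 1 without the 2 libraries, and 56 and 44 with the GC trend removed, and limma-voom gave 13 lower. Between the infected groups DESeq2 gave 674 higher, and the fit without the 2 libraries gave 185 higher and 327 lower. Of the 783, 48 and 1010 called genes, 709, 46 and 912 were shared with the calls made with the GC trend removed, and 575, 1 and 479 with those made without the 2 libraries.

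Leaving out one library at a time gave 256 (without eggs_22C replicate 3) to 680 (replicate 1) higher and 130 (without eggs_22C replicate 5) to 454 (replicate 1) lower for 22 °C eggs against uninfected. It gave 7 (without uninfected replicate 4) to 33 (eggs_37C replicate 5) higher and 8 (eggs_37C replicate 3) to 34 (eggs_37C replicate 5) lower for 37 °C eggs against uninfected. It gave 167 (eggs_22C replicate 3) to 590 (uninfected replicate 3) higher and 259 to 657 (the same libraries) lower between the infected groups. List calls for 37 °C eggs against uninfected were 3 to 8 up and 2 to 6 down. With an estimated correlation 0 lists passed up and 0 down in each comparison; fry gave 3 down for 22 °C eggs and 1 up and 0 down for 37 °C eggs, each against uninfected. The correlation of the 2 infected groups' fold changes was 0.1489 on average with split uninfected libraries (-0.0017 to 0.2674 over 20 splits). Splitting removes the shared controls but also leaves each comparison fewer uninfected libraries. The added noise lowers a correlation too, so the fall does not measure the shared controls alone.

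The genes whose log2 fold change changed sign had not passed the threshold. Arg1 after 22 °C eggs was 0.01 with the GC trend removed and 0.05 by limma-voom (-0.16 to 0.04 with a library left out). Cd4 after 22 °C eggs was 0.28 by limma-voom (-0.27 to 0.21), after 37 °C eggs -0.22 to 0.26 with a library left out, and between the infected groups -0.00 by limma-voom (-0.18 to 0.24). Retnla between the infected groups was -0.02 with the GC trend removed, -0.02 with library-size scaling and -0.86 by limma-voom (-2.24 to 0.39), and Cyp7a1 was -0.22 by limma-voom. After 37 °C eggs Col1a1 was -0.06 with the GC trend removed and -0.01 with library-size scaling (-0.33 to 0.23), Col3a1 was -0.08 to 0.20, and Alb was -0.06 without the 2 libraries (-0.11 to 0.11); between the infected groups Alb was -0.01 to 0.22. The cause was not tested.

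With the replicate number as a block, higher and lower genes numbered 426 and 215, 24 and 30, and 325 and 444 in the 3 comparisons, and 592, 39 and 724 calls were shared. The block turned Cd4 after 22 °C eggs to 0.01, Col1a1 after 37 °C eggs to -0.13 and Retnla between the infected groups to -0.58. The numbers were not taken to pair the libraries: 2 of 15 pairs with the same number had a correlation of deviations above 0.1 (-0.25 to 0.166), and 3 of 15 libraries were closest to their own number. Genes under about 0.0726 to 0.0999 CPM in a library lie below the depth's limit.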

Other observations

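The test of granulocyte precursor genes was chosen only after the rise of neutrophil genes had been seen; the lists described here were fixed beforehand.

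After 22 °C eggs against uninfected mice, 3 of 17 endothelial markers rose (4 adjusted over the list alone; list adjusted p = 0.0655), Vwf, which encodes von Willebrand factor, by 2.08 ± 0.33, Stab2 by 0.51 ± 0.11 and Pecam1 by 0.45 ± 0.13. Of 14 Kupffer cell markers the scavenger receptor gene Marco rose (1.08 ± 0.26) and Cd207 fell (adjusted p = 0.047), and of 15 stellate cell markers Vipr1 (-0.71 ± 0.15) and Rgs5 (-0.64 ± 0.18) fell; these lists did not pass (adjusted p = 0.213 and 0.475). Of 14 bile duct markers Spp1, which encodes osteopontin, rose by 1.17 ± 0.28 and Cd24a by 0.95 ± 0.27 (list adjusted p = 0.226). T cell markers (15 tested), natural killer and cytotoxic genes (9), checkpoint genes (8) and type I interferon genes (20) gave 0 calls, with list adjusted p of 0.135, 0.308, 0.308 and 0.437, while fry gave adjusted p = 0.0353 for T cell markers as higher; in this comparison 2921 genes had an unadjusted p under 0.05 and DESeq2 called 735 higher. Among 20 interferon-gamma response genes Gbp6, a guanylate-binding protein gene, fell (-0.99 ± 0.18; list adjusted p = 0.475).

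Chac1 (1.80 ± 0.38) and Asns (3.15 ± 0.83), targets of the integrated stress response, rose after 22 °C eggs and Dnajc3 fell (-0.41 ± 0.10), with list adjusted p = 0.364; Asns stood at 17.6 CPM in eggs_22C replicate 3. Of the NRF2 genes Gclc (-0.88 ± 0.20) and Gsta2 (-1.37 ± 0.32) fell and Ugdh (0.68 ± 0.17) rose (list adjusted p = 0.998). Of 16 male-biased genes 4 fell (5 fell and 1 rose adjusted over the list alone; list adjusted p = 0.101, and fry gave adjusted p = 0.0368 as lower), among them Ugt2b38 (-1.07 ± 0.20) and Hsd3b5 (-5.03 ± 1.14). Erythroid genes gave 0 calls among 6 after 22 °C eggs (2 rose adjusted over the list alone; list adjusted p = 0.0786). Their listed members summed to 357.5 to 1110 CPM, against 118.9 to 416.8 CPM in uninfected mice and 201.8 to 551.4 CPM after 37 °C eggs. Of 10 mitochondrially encoded genes 3 fell, ND4L by 1.07 ± 0.21, ND2 by 0.61 ± 0.15 and ATP6 by 0.45 ± 0.13 (6 adjusted over the list alone). The list had adjusted p = 3.69e-05, and adjusted p = 0.326 with an estimated correlation. These genes took 8.91% ± 1.41 of counts against 11.4% ± 0.976 (SD, n = 5). Cytosolic ribosomal protein genes gave 0 calls among 28, with list adjusted p = 0.000269 as higher, and adjusted p = 0.52 with an estimated correlation. After 37 °C eggs compared with 22 °C eggs, 1 mitochondrially encoded gene rose, ND4L (0.93 ± 0.21), and 0 ribosomal protein genes passed. These lists had adjusted p = 0.0058 as higher and 0.00954 as lower, and adjusted p = 0.612 and 0.751 with an estimated correlation.

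One hypothesis was that the granulocyte signal after 22 °C eggs included immature cells, since genes of primary granules are transcribed mainly in precursors. Of 10 precursor genes 6 were tested and 5 rose against uninfected mice: Mpo, Elane (5.09 ± 0.80) and Prtn3, and more weakly Cebpe (0.90 ± 0.25) and Srgn (0.53 ± 0.13), while Igsf6 did not pass (-0.58 ± 0.23). The list gave camera p = 0.000313, and p = 0.0519 with an estimated correlation. Immature granulocytes may therefore be present, but 3 of the 5 also belong to the neutrophil list whose rise prompted the test, and the other genes are expressed in further blood cells, so the 5 of 6 do not separate precursors from mature cells.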
